A study of Sus scrofa with 10 samples.

How the data were processed

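The study measured polyA RNA of pig (Sus scrofa) tissue with QuantSeq, a method that counts reads at the 3' ends of transcripts, in 10 libraries: 2 of control testis, 4 of FO grafts and 4 of GF grafts. RNA was isolated with Trizol, per the labels. The deposited table holds raw counts per gene name, as whole numbers, with 1 column per library and 27376 rows. The submitters' processing notes name the build Sscrofa11.1 and DESeq2 1.42.0, with no role for either; the aligner, the counting program and the use of strand are not given in the sources used here, so counts of antisense or overlapping genes are uncertain. The labels of the control libraries carry the same cell type and growth protocol fields as those of the grafts, and the titles were used to tell the groups apart. Columns were matched to titles by group letters and number, and the columns named F were taken as FO. Of the rows, 26849 carry a name found in the RefSeq table of the build, 13 mitochondrial protein genes were given their symbols by locus tag, and 26 rows with a date in place of a name were kept but never named. Total counts ranged from 2915534 to 7013911 per library, so that 3 counts, the floor for a gene at 0, correspond to 0.428 to 1.03 CPM in a single library.

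Genes with too few counts were removed with filterByExpr (minimum count 10), and counts were scaled with TMM factors. Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, R 4.3.3), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no threshold on the fold. GF versus FO used the 8 graft libraries, and the comparisons with control testis used all 10 libraries in a single fit, because the control group has only 2. Lists of genes, 28 in all and holding 482 genes of which 462 are in the table, were tested on log2 CPM (prior count 2) with camera of limma 3.58.1, with a preset correlation of 0.01, where at least 5 members were tested, and adjusted over the lists. The camera test compares a list with all other genes. Similarity to testis was the Pearson r over genes of each graft library with the mean of the control libraries, compared between groups with an exact two-sided permutation test of 4 against 4. Shared calls were set beside 20 simulated sets of unchanged groups. Tests, lists, gene choice and the alternatives, except those said below to be later, were fixed before the data were examined.

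Genes are named by a fixed rule. First come, for each comparison, the 12 higher and 12 lower genes with the largest log2 fold change among called genes with a symbol, groups that do not overlap and an average log2 CPM of at least 4. Second come up to 4 members with the lowest p of each list described, and then DDX4, DAZL, UCHL1, KIT, SOX9, AMH, WT1, INSL3, STAR, CYP17A1, CYP11A1, ACTA2, MYH11, COL1A1, COL4A1, PECAM1, CD68 and MKI67 wherever they were tested. A few genes that the rule selects are not named, and they still count as members of their lists. Where leaving out 1 library moved a called fold by over 1.5 times, the value without it is given, as a bound or as a ratio with its counting interval where the lower group then had 3 counts or fewer. A gene at 0 in all libraries of a group is given as a lower bound against 3 counts over that group, and a gene with 1 to 3 counts in a group as a ratio with an exact 95% counting interval.

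The methods were tested on simulated data built from the measured means, depths and spread, with 100 genes changed 2-fold and 100 changed 4-fold. For GF versus FO, edgeR recovered 12 and 67 of them with 4 false calls among 83, for GF versus control testis 3 and 46 with 3 false calls among 52, and for FO versus control testis 2 and 31 with 1 false call among 34. DESeq2 recovered more (20 and 78, 13 and 66, 10 and 54) with 29, 44 and 32 false calls among 127, 123 and 96. Far fewer genes were changed here than the 4205, 4091 and 2972 called in the data. The recovered shares therefore need not hold for the data. A list of changed genes was recovered in each comparison and an unchanged list was not. Genes were simulated independently of each other, so this does not test how the list calls hold when members are correlated. Alternatives were the DESeq2 Wald test, RLE size factors and total counts as scaling, no filter, the replicate number as a block, other libraries in the fit, a fold threshold of 1.5, a fit without robust estimation, leaving out mitochondrial and haemoglobin genes, other set tests (an estimated correlation, and fry, which tests whether the genes of a list move one way) and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out GF 3 and GF 4, leaving out FO 1 and GF 3, thinning all libraries to the lowest total, and the block for the shared calls. No sequencing batch is given in the labels, and no library was left out of the values reported.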

Results

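Pig RNA was counted per gene in 10 libraries of 3 groups, with 2 libraries of control testis, 4 of FO grafts and 4 of GF grafts. FO grafts came from fibroblasts alone, and GF grafts from germ cells and fibroblasts together. According to the labels, the cells were injected with Matrigel into the dorsal skin of a mouse, and the tissue was taken 6 months later. Counts are on pig genes, so cells of the mouse may be missed or counted in part, and the species of the reads was not tested. Lower counts of blood, vessel or immune genes in grafts therefore do not show that such cells were absent. The titles of the control testis libraries carry the code 5D, which the labels do not explain, so that their age is not known here. The design asks whether the germ cells change how the tissue is remodelled. The total count was 5844944 and 7013911 in the control libraries, 4033509 to 4887878 in FO and 2915534 to 4917325 in GF. Values below are counts per 1000000 counts of a library (CPM) with TMM scaling, given as mean ± SD (n = 2 for control, n = 4 for each graft group), and log2 fold changes carry their SE. Intervals and floors rest on counts pooled over a group, so they cover counting error only and leave out the spread between libraries. They also treat reads as independent, which reads without molecular identifiers are not. The labels do not say that replicates are separate animals or cultures, so p-values measure the spread between samples, which may be technical.

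GF 3 and GF 4 lay farthest from the rest on the first principal component, which held 46.3% of the variance. These 2 libraries had the lowest totals, 2915534 and 2948156, and the highest share of counts on tRNA genes, 0.183% and 0.75%, against at most 0.0601% elsewhere. Mitochondrial genes took 6.73 ± 0.718% of the counts in GF and 9.96 ± 1.75% in FO (SD, n = 4, exact two-sided permutation p = 0.0286, BH-adjusted 0.0857 over 6 measures). Ribosomal protein genes took 9.20 ± 1.13% in GF and 15.5 ± 0.659% in FO, with the same p-values in the same exact test, and 10.2% and 11.7% in the control libraries. Skeletal muscle genes summed to 872 CPM in FO 1 and 328 CPM in GF 3, against 9.62 to 47.4 CPM in the other libraries.

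**Figure D1:**
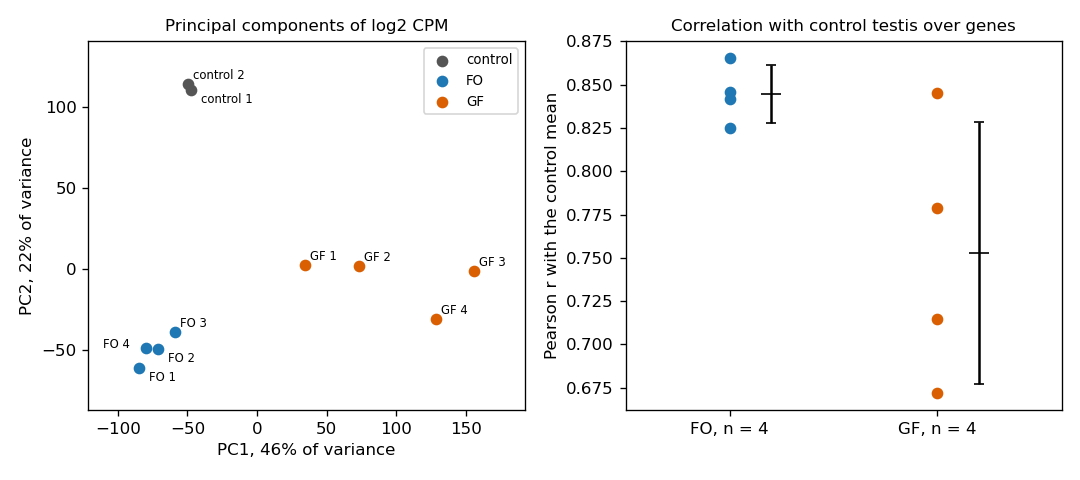
Left, principal components of log2 CPM, 1 point per library, coloured by group. Right, Pearson r over genes of each graft library with the control mean, with the group mean and SD beside the points. GF 3 and GF 4 lie farthest right, and the FO points sit above the GF mean of 0.753. The groups overlap, as GF 1 (0.845) lies above FO 1 (0.825) and FO 4 (0.842).

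The comparison of GF with FO addresses the design's question. Several germ cell genes that stood at a few counts or none in FO rose in GF. DDX4, a germ cell RNA helicase, averaged 66.1 ± 24.6 CPM in GF and 1.15 ± 0.777 CPM in FO, a log2 fold change of 5.78 ± 0.48 (adjusted p = 5.53e-05). PIWIL1, a piRNA-binding protein of spermatocytes and spermatids, averaged 247 ± 150.4 CPM in GF and 0.975 ± 0.533 CPM in FO (7.9 ± 0.57, adjusted p = 2.96e-05).

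For spermatogonia and other early germ cells, of 17 tested members 10 rose and 7 did not pass (10 rose adjusted over the list alone). The list was higher in GF (adjusted p = 5.04e-04, and adjusted p = 0.142 with an estimated correlation). Besides DDX4, its members DAZL (5.44), PIWIL2 (4.72) and MAEL (5.08) rose, and MOV10L1 rose 211-fold (95% counting interval 71.7 to 1025). UCHL1 averaged 46.4 ± 14 CPM in GF and 55 ± 20.8 CPM in FO and did not pass (adjusted p = 0.577), and neither did KIT, at 73.4 ± 12.8 and 70.1 ± 19.1 CPM (adjusted p = 0.856). Among meiosis and spermatid genes, of 17 tested members 15 rose and 2 did not pass (15 rose adjusted over the list alone), with adjusted p = 3.10e-12, and adjusted p = 0.276 with an estimated correlation. HORMAD1, a protein of meiotic chromosomes, rose by 4.73 on the log2 scale, TEX101 by 6.44 and TNP1, which replaces histones in spermatids, by 10.08. The protamine PRM2 had 116 ± 124 CPM in GF and rose 896-fold (95% counting interval 248 to 7401), the acrosomal protease ACR 1274-fold (95% counting interval 228 to 50362), and outside the list HMGB4 1281-fold (95% counting interval 229 to 50624) and HSPB9 1144-fold (95% counting interval 205 to 45213). Against a floor of 3 counts over the 4 FO libraries, all of which were at 0, the list member ODF1, a sperm tail protein, was at least 187-fold higher. By the same floor, outside the list, GK2 was at least 334-fold, CCDC83 at least 194-fold, ACTRT2 at least 166-fold, TEX44 at least 181-fold, DNAJC5G at least 159-fold and COMP, a cartilage matrix protein, at least 157-fold higher. In the cell division list, of 18 tested members 11 rose and 7 did not pass (12 rose adjusted over the list alone), with adjusted p = 2.28e-04, and adjusted p = 0.301 with an estimated correlation. Its members PLK1 (4.24), BUB1B (3.07), TOP2A (3.02), MKI67 (2.72) and BIRC5 (2.2) rose. Germ cell values varied between the GF libraries, with 403, 2404, 2776 and 423 counts of PRM1 in GF 1 to GF 4. Leaving out FO 1 moved TNP1 (to at least 1188-fold higher), HMGB4 (to at least 340.2-fold higher), HSPB9 (to at least 304-fold higher) and PRM2 (to at least 476-fold higher). Leaving out FO 2 moved MOV10L1 (to 468-fold higher, interval 83.6 to 18501) and TEX101 (to 234-fold higher, interval 79.9 to 1139). Leaving out FO 3 moved ACR (to at least 310.1-fold higher). Leaving out FO 4 moved PIWIL2 (to 5.35). Leaving out GF 3 moved COMP (to at least 51.3-fold higher), ACTRT2 (to at least 90.4-fold higher), TNP1 (to 9.13), ACR (to 835-fold higher, interval 149 to 33042), HSPB9 (to 708-fold higher, interval 127 to 28032) and PRM2 (to 517-fold higher, interval 143 to 4280.5).

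**Figure D2:**
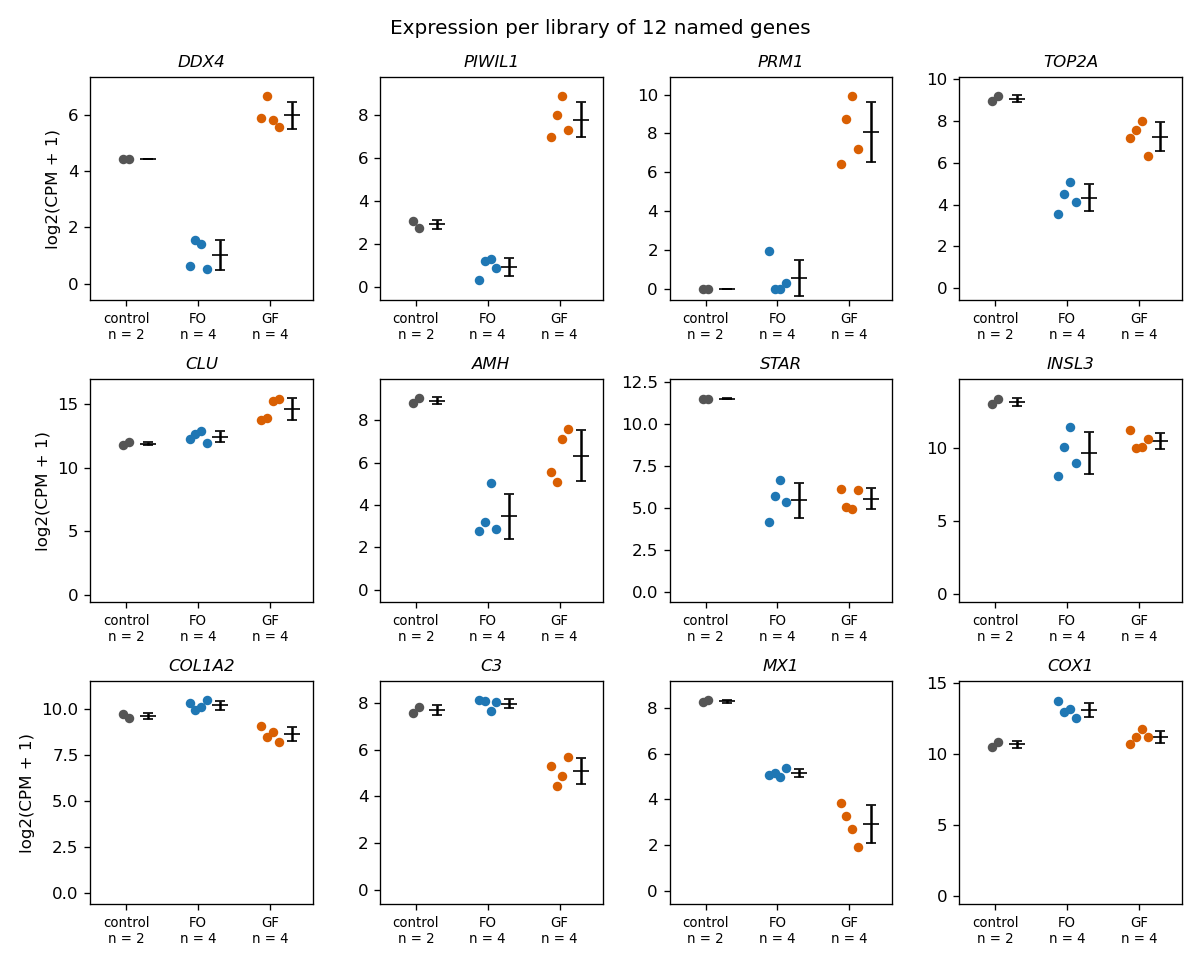
log2(CPM + 1) of 12 named genes, 1 point per library, with the group mean and SD of these log values beside the points. DDX4, PIWIL1 and PRM1 are near 0 in FO and high in GF, and STAR and INSL3 are highest in the control libraries.

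In the fibroblast and fibrillar matrix list, of 25 tested members 3 rose, 12 fell and 10 did not pass (3 rose and 15 fell adjusted over the list alone), with adjusted p = 0.00161, and adjusted p = 0.357 with an estimated correlation. COL1A1 (-0.93 ± 0.27, adjusted p = 0.0215) and COL1A2 (-1.55), the chains of type I collagen, fell, as did POSTN (-2.42) and the nuclear receptor NR2F2 (-2.3), while ELN, the elastin gene, rose (3.35). In the macrophage and other myeloid cell list, of 12 tested members 8 fell and 4 did not pass (9 fell adjusted over the list alone), with adjusted p = 5.04e-04, and adjusted p = 0.301 with an estimated correlation. CD14 (-3.08), C1QB (-4.29), C1QC (-3.34) and CTSS (-1.89) fell. CD68 was too low to be tested. In the complement, chemokine and cytokine list, of 11 tested members 1 rose, 6 fell and 4 did not pass (1 rose and 7 fell adjusted over the list alone), with adjusted p = 5.04e-04, and adjusted p = 0.301 with an estimated correlation. C3, the central complement component, averaged 34.6 ± 13 CPM in GF and 249.6 ± 33.6 CPM in FO (-2.85), and C1R (-2.94), SERPING1 (-1.41) and CFB (-4.84) also fell. In the list of signals of the germ cell niche, of 13 tested members 6 fell and 7 did not pass (7 fell adjusted over the list alone), with adjusted p = 0.00161, and adjusted p = 0.301 with an estimated correlation. FGF2 (-2.27), BMP4 (-2.18), IGF1 (-1.49) and NRG1 (-1.77) fell. Of the mitochondrial genome, of 13 tested members 10 fell and 3 did not pass (11 fell adjusted over the list alone), with adjusted p = 5.04e-04, and adjusted p = 0.357 with an estimated correlation. ND2 (-1.59), COX1 (-1.91), ND3 (-1.1) and ATP8 (-1.21) fell. Outside these lists, named genes that fell included the collectin COLEC11 (-3.78), OLFM3 (-3.78), BST1 (-3.54), the connexin GJA5 (-3.49), S100A4 (-3.46), SEL1L3 (-3.36), CP, which encodes ceruloplasmin (-3.34), SYNDIG1L (-3.18) and the interleukin receptor IL1R1 (-3.16). Complement factor I, CFI, averaged 93.3 ± 64.8 CPM in GF and 964 ± 357 CPM in FO (-3.37 ± 0.50, adjusted p = 7.18e-04), and SPP1, which encodes osteopontin, 29.2 ± 29.7 and 332 ± 118 CPM (-3.49). Leaving out FO 4 moved C1QC (to -2.54). Leaving out GF 1 moved BST1 (to -5.67), SEL1L3 (to -4.08) and IL1R1 (to -4.05). Leaving out GF 2 moved SPP1 (to -4.21), C1QB (to 32.5-fold lower, interval 10.9 to 159) and CFB (to 62.4-fold lower, interval 17.1 to 519).

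The Sertoli cell list split, as of 17 tested members 6 rose, 3 fell and 8 did not pass (8 rose and 4 fell adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.349). CLU, which encodes the chaperone clusterin, averaged 28115 ± 15637 CPM in GF and 5734 ± 1685 CPM in FO (2.3 ± 0.40, adjusted p = 0.00159), and took 3.89% and 4.31% of the counts of GF 3 and GF 4 against 1.51% and 1.77% in GF 1 and GF 2. AMH, the anti-Müllerian hormone, rose (2.95 ± 0.67, adjusted p = 0.00662), as did MRO (2.42) and SOX9 (0.91), while WT1 (-1.13), LHX9 (-2.68) and KRT8 (-1.54) fell. Of the Leydig cell and steroidogenesis list, of 16 tested members 2 rose, 1 fell and 13 did not pass (1 rose adjusted over the list alone) (list adjusted p = 0.113). HSD17B3, the enzyme that makes testosterone from androstenedione, rose (2.43), as did the steroidogenic regulator NR5A1 (1.53, adjusted p = 0.0326), and HSD3B1 fell (-1.21, adjusted p = 0.0498). INSL3, a Leydig cell hormone, averaged 1533 ± 637 CPM in GF and 1152 ± 1128 CPM in FO and did not pass, nor did STAR at 49.9 ± 21 and 52.7 ± 35.4 CPM, CYP11A1 at 230.0 ± 78.5 and 243 ± 140.1 CPM, or CYP17A1 at 220.2 ± 167 and 95.8 ± 87.8 CPM. Of the peritubular myoid and smooth muscle list, of 15 tested members 6 rose and 9 did not pass (6 rose adjusted over the list alone) (list adjusted p = 0.113), and MYH11 (2.57), ACTA2 (1.29), TAGLN (1.36) and CNN1 (2.55), all of the contractile apparatus, rose. Of the basement membrane list, of 15 tested members 3 rose, 3 fell and 9 did not pass (3 rose and 4 fell adjusted over the list alone) (list adjusted p = 0.902), with COL4A1 (2.25), COL4A2 (1.82) and LAMA1 (1.56) higher and LAMA5 (-1.49) lower. Of the endothelial cell list, of 13 tested members 2 fell and 11 did not pass (2 fell adjusted over the list alone) (list adjusted p = 0.249). EMCN (-3.17) and CD34 (-1.29) fell, and PECAM1 at 13.7 ± 6.83 and 23.4 ± 16.2 CPM did not pass. Leaving out FO 3 moved AMH (to 3.91). Leaving out FO 4 moved CNN1 (to 3.16).

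In all, edgeR called 4205 of 13782 genes, 2419 higher and 1786 lower in GF. Of these, 3823 had groups that did not overlap, and groups did not overlap for 36.1% of the tested genes, where chance gives 2.86%. Of 23 lists tested with camera 8 were called, 3 higher and 5 lower, and with an estimated correlation 0 were, the lowest adjusted p being 0.142. With total counts alone as scaling, 69.1% of the calls were higher, against 57.5% with TMM, and the median of all genes moved to 0.13 from -0.02 on the log2 scale. Without FO 1 and GF 3, the libraries with skeletal muscle transcripts, 2312 genes were called, and against a fold of 1.5 there were 2456. Calls that ended without at least 1 single library were those of HSD3B1 (adjusted p up to 0.151, without FO 4), NR5A1 (0.0994, without FO 1), COL1A1 (0.0815, without FO 4), CD34 (0.0578, without FO 4) and C1QC (0.0536, without FO 4), and CYP17A1 passed without FO 3 (0.0281). Without GF 3 and GF 4, 5305 genes were called, 3562 of them among the 4205, but AMH, NR5A1, HSD3B1 and CTSS did not pass (adjusted p = 0.127, 0.351, 0.11 and 0.071). With total counts alone, COL1A1 (0.0553) and HSD3B1 (0.115) lost the call. Against a fold of 1.5, SOX9 (0.0901), COL1A1 (0.134), NR5A1 (0.0863), HSD3B1 (0.133) and CD34 (0.0562) lost the call. At equal totals, HSD3B1 (0.0797) lost the call. With the replicate number as a block, HSD3B1 (0.0637) lost the call. With the replicate number as a block, CYP17A1 (0.0358) passed. Without FO 1 and GF 3, AMH (0.0679), COL1A1 (0.0956), MKI67 (0.0549), NR5A1 (0.201), CNN1 (0.0782), LAMA1 (0.0613), CTSS (0.0637) and C1QC (0.0507) lost the call. Without mitochondrial and haemoglobin genes, HSD3B1 (0.0528) lost the call.

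**Figure D3:**
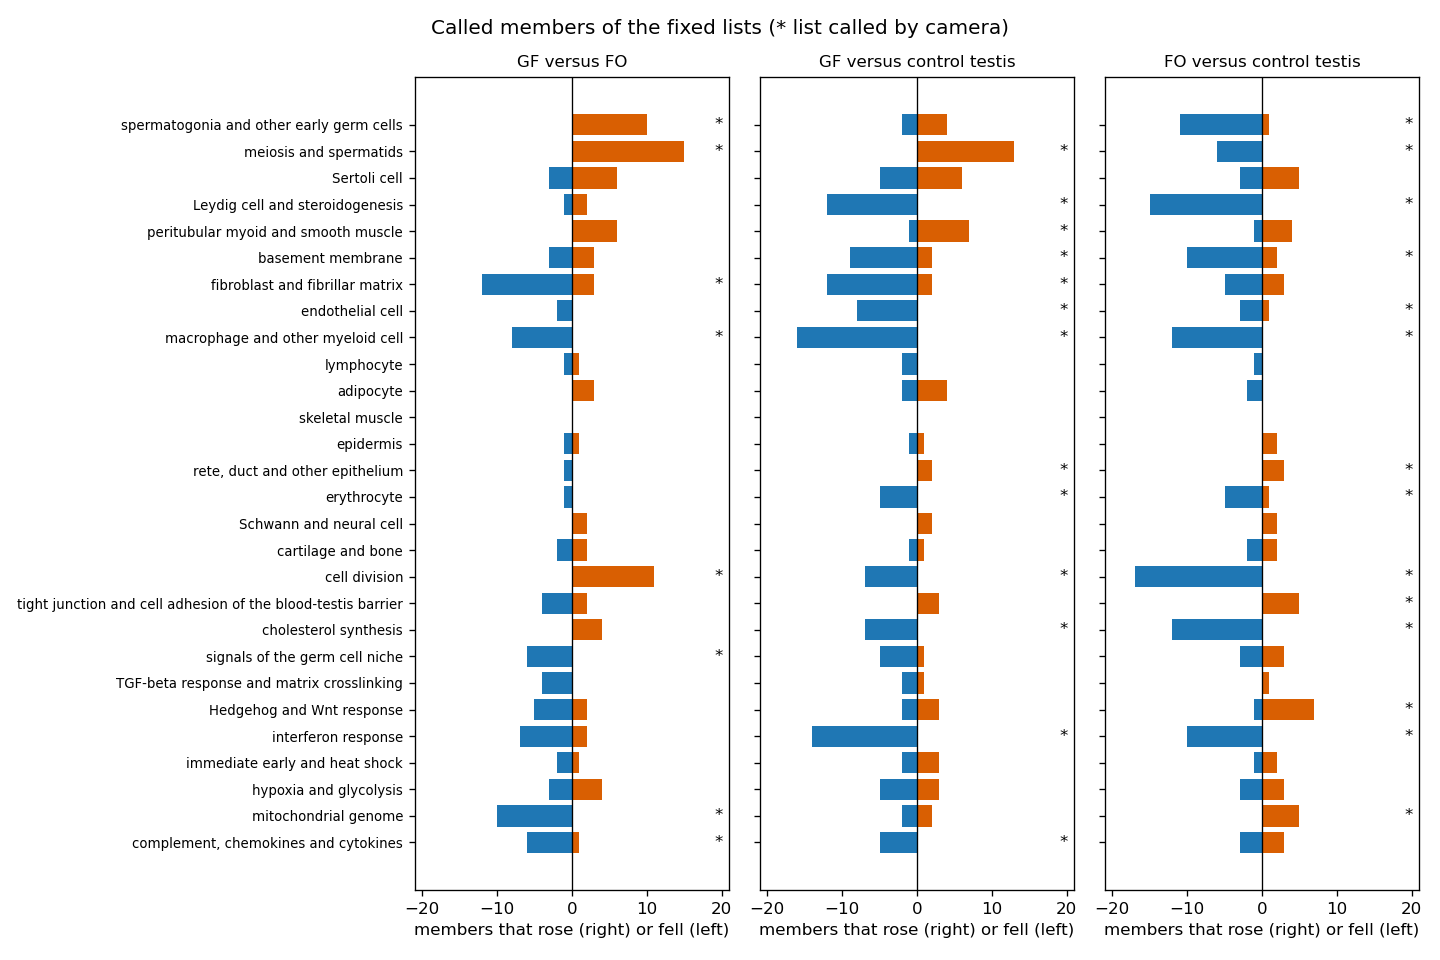
Members of each fixed list that rose (bars to the right) or fell (bars to the left) in each comparison, as numbers of genes, with an asterisk where camera called the list at an adjusted p of 0.05. In GF versus FO, 15 members of the meiosis and spermatid list rose and 8 of the myeloid list fell.

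The comparisons with control testis show how far each graft differs from these 2 control libraries, whose age is not known here. A difference in age therefore cannot be told apart from a difference in tissue. GF grafts carried several spermatid transcripts that stood at 0 or a few counts in the control libraries. PRM1, the protamine that packs sperm DNA, averaged 406 ± 398 CPM in GF and 0 counts in both control libraries, at least 1588-fold higher. STAR, which carries cholesterol into mitochondria for steroid synthesis, averaged 49.9 ± 21 CPM in GF and 2932 ± 39.7 CPM in control testis (-5.88 ± 0.54, adjusted p = 2.09e-05). The haemoglobin chain HBB had 3 counts over the 4 GF libraries and 3469.9 ± 615 CPM in control testis. Leaving out GF 3 moved PRM1 (to at least 1043-fold higher). Without control 1 or control 2 the bounds against control testis were 1.92 and 2.09 times smaller, since the floor then rests on 1 library.

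Among meiosis and spermatid genes, of 20 tested members 13 rose and 7 did not pass (13 rose adjusted over the list alone), with adjusted p = 3.71e-08, and adjusted p = 0.186 with an estimated correlation. Besides PRM1, its member PRM2 was at least 428-fold higher in GF by the floor of 3 counts over the group. By the same floor, the following genes of no list were higher, PRM3 at least 216-fold, CATSPERZ, of the sperm calcium channel, at least 239-fold, CCER1 at least 191-fold, GK2 at least 239.8-fold, TMIGD3 at least 252-fold and CILP2 at least 159-fold. Of the list, TNP1 rose 1070.0-fold (95% counting interval 366 to 5191), ACR 457-fold (95% counting interval 126 to 3779.5), and PIWIL1 (5.22) and TEX101 (7.22) rose, and outside it HMGB4 rose 919-fold (95% counting interval 165 to 36333), HSPB9 821-fold (95% counting interval 147 to 32449.5) and ANKRD35 by 9.04 on the log2 scale. For spermatogonia and other early germ cells, of 20 tested members 4 rose, 2 fell and 14 did not pass (5 rose and 2 fell adjusted over the list alone), and the list did not pass (adjusted p = 0.423). DDX4 (1.67 ± 0.45, adjusted p = 0.0158), ID4 (3.84), MOV10L1 (4.16) and ZBTB16 (1.86) rose and GFRA1, the GDNF receptor of spermatogonia, fell (-2.94). DAZL at 44.8 ± 30.2 and 13.3 ± 0.852 CPM and UCHL1 at 46.4 ± 14 and 38.1 ± 1.44 CPM did not pass, and KIT fell (-3.28). In the Sertoli cell list, of 18 tested members 6 rose, 5 fell and 7 did not pass (7 rose and 5 fell adjusted over the list alone) (list adjusted p = 0.207). PTGDS (5.69), MRO (4.95), CLU (2.87), SOX9 (1.38) and WT1 (1.04) rose and AMH fell (-2.28). Leaving out control 1 moved TNP1 (to 1675-fold higher, interval 300.5 to 66177), HMGB4 (to at least 159.9-fold higher), HSPB9 (to at least 143-fold higher) and TEX101 (to 356-fold higher, interval 63.7 to 14072). Leaving out control 2 moved HMGB4 (to 439.5-fold higher, interval 78.7 to 17374), HSPB9 (to 392-fold higher, interval 70.3 to 15517), MOV10L1 (to 5.03) and TEX101 (to 109-fold higher, interval 37.1 to 528). Leaving out GF 3 moved PRM2 (to at least 248-fold higher), PRM3 (to at least 92.6-fold higher), CCER1 (to at least 55.5-fold higher), CILP2 (to at least 94.9-fold higher), TNP1 (to 670.5-fold higher, interval 229 to 3254), HSPB9 (to 508-fold higher, interval 90.9 to 20119), ANKRD35 (to 7.73) and ACR (to 299.7-fold higher, interval 82.6 to 2480.4). Without control 1 or control 2 the bounds against control testis were 1.92 and 2.09 times smaller, since the floor then rests on 1 library.

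In the Leydig cell and steroidogenesis list, of 17 tested members 12 fell and 5 did not pass (12 fell adjusted over the list alone), with adjusted p = 9.13e-05, and adjusted p = 0.329 with an estimated correlation. CYP19A3 (-6.01), an aromatase whose reads may be shared with its paralogs, FDX1 (-3.55), SCARB1 (-3.47), CYP11A1 (-2.86), CYP17A1 (-2.02) and INSL3 (-2.63) fell. In the cholesterol synthesis list, of 14 tested members 7 fell and 7 did not pass (8 fell adjusted over the list alone), with adjusted p = 5.66e-04, and adjusted p = 0.218 with an estimated correlation. MSMO1 (-2.68), FDPS (-2.44) and HMGCS1 (-1.33) fell. In the macrophage and other myeloid cell list, of 18 tested members 16 fell and 2 did not pass (17 fell adjusted over the list alone), with adjusted p = 1.47e-09, and adjusted p = 0.186 with an estimated correlation. C1QA (-6.76), C1QB (-6.77), C1QC (-5.61), SLA-DRA (-4.81), LAPTM5 (-4.24), CTSS (-3.74) and CD68 (-5.35) fell. In the interferon response list, of 18 tested members 14 fell and 4 did not pass (15 fell adjusted over the list alone), with adjusted p = 5.66e-09, and adjusted p = 0.00709 with an estimated correlation, so that this list held in both tests. MX1 (-5.31), OAS2 (-2.95) and ISG15 (-2.98) fell and RSAD2 fell 287-fold (95% counting interval 79 to 2376), as did IFITM3 (-4.81), IFIH1 (-4.81) and GIMAP1 (-5.7) outside the list. In the complement, chemokine and cytokine list, of 14 tested members 5 fell and 9 did not pass (5 fell adjusted over the list alone), with adjusted p = 5.66e-04, and adjusted p = 0.186 with an estimated correlation. C3 (-2.58), C1R (-2.78), CCL2 (-2.64) and CXCL14 (-5.05) fell. In the erythrocyte list, of 7 tested members 5 fell and 2 did not pass (1 rose and 5 fell adjusted over the list alone), with adjusted p = 5.66e-04, and adjusted p = 0.186 with an estimated correlation. HBB fell 18600.4-fold (95% counting interval 6364 to 90199), and HBM (-6.81), ALAS2 (-6.6) and AHSP (-2.55) fell. These are counts on pig genes, and blood of the mouse may not be among them. FBP2, a gluconeogenic enzyme, fell by 7.49 on the log2 scale. Leaving out GF 1 moved HBB (to 39523-fold lower, interval 7093 to 1561100.0), ALAS2 (to 357-fold lower, interval 122 to 1733), CD68 (to 263-fold lower, interval 46.8 to 10406), CCL2 (to -3.3) and CXCL14 (to 387-fold lower, interval 69 to 15310.0). Leaving out GF 2 moved C1QA (to -7.35), C1QB (to 193-fold lower, interval 65.8 to 939), HBM (to 291-fold lower, interval 80.1 to 2404) and RSAD2 (to at least 125-fold lower). Leaving out GF 4 moved FBP2 (to -8.37) and CYP17A1 (to -2.65).

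In the fibroblast and fibrillar matrix list, of 25 tested members 2 rose, 12 fell and 11 did not pass (3 rose and 16 fell adjusted over the list alone), with adjusted p = 6.10e-04, and adjusted p = 0.316 with an estimated correlation. DPT (-3.5), COL3A1 (-2.82), FBN1 (-2.76) and FAP (-2.53) fell, while COL1A1 at 809.8 ± 237 and 1061 ± 120.2 CPM did not pass. In the basement membrane list, of 15 tested members 2 rose, 9 fell and 4 did not pass (2 rose and 10 fell adjusted over the list alone), with adjusted p = 0.00147, and adjusted p = 0.186 with an estimated correlation. The laminin chains LAMB1 (-2.38), LAMA2 (-2.21) and LAMC1 (-1.74) and perlecan, HSPG2 (-1.87), fell, and COL4A1 at 378 ± 182 and 709 ± 43.4 CPM did not pass. In the endothelial cell list, of 15 tested members 8 fell and 7 did not pass (8 fell adjusted over the list alone), with adjusted p = 5.66e-04, and adjusted p = 0.32 with an estimated correlation. PECAM1 (-2.77), ROBO4 (-4.21), ERG (-2.66) and KDR (-2.31) fell. In the cell division list, of 21 tested members 7 fell and 14 did not pass (11 fell adjusted over the list alone), with adjusted p = 6.10e-04, and adjusted p = 0.316 with an estimated correlation. MCM2 (-2.68), MCM4 (-2.01), MCM3 (-1.96), TOP2A (-1.71) and MKI67 (-1.81) fell. In the peritubular myoid and smooth muscle list, of 15 tested members 7 rose, 1 fell and 7 did not pass (7 rose and 1 fell adjusted over the list alone), with adjusted p = 0.0234, and adjusted p = 0.329 with an estimated correlation. The list also lost its call with the replicate number as a block (0.085), without GF 4 (0.0579) and without GF 3 and GF 4 (0.0969). MYH11 (3.15), TPM1 (1.35), TAGLN (1.17) and MYLK (1.12) rose, and ACTA2 at 244 ± 40.9 and 207 ± 39.6 CPM did not pass. Of rete, duct and other epithelial genes, of 5 tested members 2 rose and 3 did not pass (3 rose adjusted over the list alone), with adjusted p = 0.0361, and adjusted p = 0.186 with an estimated correlation. KRT7 (5.66) and KRT19 (3.2) rose. Leaving out GF 1 moved ROBO4 (to -6.32).

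In all, 4091 of 15877 genes were called in GF versus control testis, 2221 higher and 1870 lower, and 13 of 27 lists, 3 higher and 10 lower. With an estimated correlation 1 list was called, that of the interferon response. Groups did not overlap for 47.2% of the genes, where chance gives 13.3%. The count was 1395 without control 1 and 1141 without control 2, 2658 against a fold of 1.5 and 2201 when only the 6 libraries compared entered the fit. Without either control library, the calls of CCER1, DDX4, AMH, WT1, CYP17A1, MKI67, TPM1, MYLK, TAGLN, ROBO4, KDR and MCM3 ended (adjusted p from 0.056 to 0.163), and without control 2 alone also those of SOX9, INSL3, ZBTB16, GFRA1, ERG, AHSP, MCM4 and TOP2A (0.0524 to 0.085). CYP17A1 also ended without GF 1, GF 2 or GF 3 (0.0724, 0.0737 and 0.0713), and DAZL passed without GF 4 (0.0103). Without GF 3 and GF 4, 5677 genes were called, 3709 of them among the 4091, and INSL3, CYP17A1 and ROBO4 did not pass (0.173, 0.0709 and 0.155) while DAZL and COL4A1 did (2.36e-04 and 0.00606). With DESeq2, AMH (0.0504), CYP17A1 (0.085) and ROBO4 (0.0536) lost the call. Without a filter, CCER1 (0.0605), AMH (0.0847), INSL3 (0.0522), CYP17A1 (0.142) and ROBO4 (0.0646) lost the call. With only the 6 libraries compared, WT1 (0.0505) and KDR (0.0782) lost the call. Against a fold of 1.5, WT1 (0.0795), CYP17A1 (0.0817), MKI67 (0.056) and TAGLN (0.0545) lost the call. At equal totals, CYP17A1 (0.0506) lost the call. With the replicate number as a block, DAZL (0.00781) and COL4A1 (0.0021) passed. Without FO 1 and GF 3, CYP17A1 (0.0669) lost the call.

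In the comparison of FO grafts with control testis, STAR averaged 52.7 ± 35.4 CPM in FO and 2932 ± 39.7 CPM in control testis (-5.79 ± 0.54, adjusted p = 2.12e-05). TOP2A, a topoisomerase of dividing cells, averaged 20.5 ± 9.41 CPM in FO and 543 ± 57.3 CPM in control testis (-4.72 ± 0.44, adjusted p = 2.12e-05). CFI averaged 964 ± 357 CPM in FO and 8.8 ± 1.55 CPM in control testis (6.77 ± 0.78, adjusted p = 8.59e-05).

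For spermatogonia and other early germ cells, of 20 tested members 1 rose, 11 fell and 8 did not pass (1 rose and 11 fell adjusted over the list alone), with adjusted p = 0.00104, and adjusted p = 0.104 with an estimated correlation. DDX4 (-4.11), DAZL (-3.69), PIWIL2 (-4.33) and DND1 (-3.51) fell and ID4 rose (4.23), while UCHL1 at 55 ± 20.8 and 38.1 ± 1.44 CPM did not pass and KIT fell (-3.34). Among meiosis and spermatid genes, of 20 tested members 6 fell and 14 did not pass (6 fell adjusted over the list alone), with adjusted p = 0.0428, and adjusted p = 0.648 with an estimated correlation. The list also lost its call with fry (0.115), without a filter (0.0755), without control 1 (0.083), without FO 3 (0.0566), without FO 4 (0.0583) and at equal totals (0.0645). SYCP3 (-5.5) and SYCP1 (-3.59), of the synaptonemal complex, PIWIL1 (-2.67) and HORMAD1 (-2.01) fell. TEX15 (-6.03) and ART3 (-5.03) fell outside the lists, and BRDT, a bromodomain protein of the testis, fell 132-fold (95% counting interval 44.8 to 646). In the cell division list, of 21 tested members 17 fell and 4 did not pass (20 fell adjusted over the list alone), with adjusted p = 1.51e-11, and adjusted p = 0.104 with an estimated correlation. MKI67 (-4.52), BUB1B (-4.15) and CCNB1 (-3.69) fell beside TOP2A. In the Leydig cell and steroidogenesis list, of 17 tested members 15 fell and 2 did not pass (15 fell adjusted over the list alone), with adjusted p = 4.87e-08, and adjusted p = 0.223 with an estimated correlation. CYP19A3 (-7.58), SCARB1 (-4.6), CYP17A1 (-3.22), INSL3 (-3.04), CYP11A1 (-2.77) and POR (-2.22) fell. In the cholesterol synthesis list, of 14 tested members 12 fell and 2 did not pass (13 fell adjusted over the list alone), with adjusted p = 2.13e-06, and adjusted p = 0.104 with an estimated correlation. MSMO1 (-2.61), FDPS (-2.51) and HMGCS1 (-1.31) fell. In the Sertoli cell list, of 18 tested members 5 rose, 3 fell and 10 did not pass (5 rose and 3 fell adjusted over the list alone) (list adjusted p = 0.353). AMH (-5.21) and CITED1 (-2.31) fell, PTGDS (5.51) and WT1 (2.17) rose, and SOX9 at 258 ± 31.2 and 186 ± 16.8 CPM did not pass. FBP2 was at 0 in all FO libraries, at least 639-fold lower, and TMSB15A (-5.24) and KIAA1644 (-4.95) fell. Leaving out FO 2 moved BRDT (to 294-fold lower, interval 52.3 to 11644), SYCP3 (to -6.26), ART3 (to -5.66) and SYCP1 (to -4.29). Leaving out FO 3 moved CYP19A3 (to -9.84), TEX15 (to -6.79), TMSB15A (to -6.2), AMH (to -6.15), INSL3 (to -3.95) and CYP17A1 (to -4.06). Leaving out FO 4 moved PIWIL2 (to -4.95).

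In the macrophage and other myeloid cell list, of 18 tested members 12 fell and 6 did not pass (12 fell adjusted over the list alone), with adjusted p = 8.03e-05, and adjusted p = 0.247 with an estimated correlation. LYZ (-4.21), LAPTM5 (-2.91), SLA-DRA (-2.52), CD68 (-2.45) and CTSS (-1.86) fell. In the interferon response list, of 18 tested members 10 fell and 8 did not pass (14 fell adjusted over the list alone), with adjusted p = 3.54e-07, and adjusted p = 0.0155 with an estimated correlation, so that this list held in both tests, and MX1 (-3.19), HERC5 (-3.05), USP18 (-2.67) and ISG15 (-2.54) fell. In the erythrocyte list, of 7 tested members 1 rose, 5 fell and 1 did not pass (1 rose and 5 fell adjusted over the list alone), with adjusted p = 3.14e-04, and adjusted p = 0.115 with an estimated correlation. HBB (-8.76), ALAS2 (-4.82) and AHSP (-3.55) fell, HBM was at least 327-fold lower, and HBE1, an embryonic globin, rose 103-fold (95% counting interval 35 to 502). In the basement membrane list, of 15 tested members 2 rose, 10 fell and 3 did not pass (2 rose and 11 fell adjusted over the list alone), with adjusted p = 0.00104, and adjusted p = 0.117 with an estimated correlation. COL4A1 (-3.15), HSPG2 (-2.65), COL4A2 (-2.61) and LAMB1 (-2.27) fell. In the endothelial cell list, of 15 tested members 1 rose, 3 fell and 11 did not pass (1 rose and 3 fell adjusted over the list alone), with adjusted p = 0.0251, and adjusted p = 0.572 with an estimated correlation. The list also lost its call with fry (0.104), without a filter (0.055) and without FO 2 (0.0743). VWF (-2.77), PECAM1 (-2.0) and ERG (-1.92) fell while EMCN rose (2.31). In the fibroblast and fibrillar matrix list, of 25 tested members 3 rose, 5 fell and 17 did not pass (3 rose and 6 fell adjusted over the list alone) (list adjusted p = 0.793). LUM (-4.17), DPT (-3.52) and FAP (-1.89) fell, POSTN rose (3.57), and COL1A1 at 1545 ± 463 and 1061 ± 120.2 CPM did not pass. Of smooth muscle genes, ACTA2 fell (-1.05) and MYH11 at 29.7 ± 11.8 and 19.7 ± 1.32 CPM did not pass. Leaving out FO 3 moved LUM (to -5.38). Leaving out FO 4 moved HBB (to -9.8), ALAS2 (to -7.4), PECAM1 (to -2.6), VWF (to -3.51), ERG (to -2.69), SLA-DRA (to -3.13) and HBE1 (to 50.9-fold higher, interval 17.1 to 249.6).

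Lists that were higher in FO covered epithelium, cell junctions, Wnt and the mitochondrial genome. Of rete, duct and other epithelial genes, of 5 tested members 3 rose and 2 did not pass (3 rose adjusted over the list alone), with adjusted p = 0.00459, and adjusted p = 0.104 with an estimated correlation. KRT7 (5.84), KRT19 (3.87) and CDH1 (2.92) rose. In the list of tight junctions and cell adhesion, of 13 tested members 5 rose and 8 did not pass (5 rose adjusted over the list alone), with adjusted p = 0.00345, and adjusted p = 0.231 with an estimated correlation. CLDN1 (6.04), CDH2 (2.12) and JAM3 (1.6) rose. In the Hedgehog and Wnt response list, of 16 tested members 7 rose, 1 fell and 8 did not pass (8 rose and 2 fell adjusted over the list alone), with adjusted p = 0.00452, and adjusted p = 0.104 with an estimated correlation. The Wnt antagonists SFRP2 (3.31) and SFRP1 (3.09), the Wnt amplifier RSPO3 (4.18) and the Wnt target AXIN2 (2.25) rose. Of the mitochondrial genome, of 13 tested members 5 rose and 8 did not pass (5 rose adjusted over the list alone), with adjusted p = 0.00154, and adjusted p = 0.376 with an estimated correlation. ATP8 (4.12), COX1 (2.49), ND6 (2.31) and ND1 (1.16) rose. In the list of niche signals, of 14 tested members 3 rose, 3 fell and 8 did not pass (4 rose and 3 fell adjusted over the list alone) (list adjusted p = 0.596), with IGF1 (3.68), BMP4 (2.75) and FGF2 (2.18) higher and CXCL12 (-2.94) lower. Beside CFI, named genes outside the lists that rose were CRB2 (8.34), DCDC2 (7.06), the adhesion molecule CHL1 (6.92), GAL3ST3 (6.7), STK32A (6.64), the GABA receptor subunit GABBR2 (6.63), EFEMP1 (6.4) and CRTAC1 (6.16), and the cadherin CDH20 rose 189-fold (95% counting interval 52.2 to 1569). Leaving out control 1 moved CDH20 (to 98.9-fold higher, interval 27.2 to 819), GAL3ST3 (to 279-fold higher, interval 77.2 to 2309), GABBR2 (to 7.73), EFEMP1 (to 157-fold higher, interval 43.5 to 1302) and CDH1 (to 3.56). Leaving out control 2 moved CDH20 (to at least 60.4-fold higher), GAL3ST3 (to 5.98), GABBR2 (to 5.97) and ATP8 (to 4.72).

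In all, 2972 of 15877 genes were called in FO versus control testis, 1290 higher and 1682 lower, and 14 of 27 lists, 4 higher and 10 lower. With an estimated correlation 1 list was called, again that of the interferon response. Groups did not overlap for 58.7% of the genes, where chance gives 13.3%. The count was 6510 without GF 3 and GF 4 (2954 of them among the 2972), 6600 with only the 6 libraries compared, 977 without control 1, 796 without control 2 and 1833 against a fold of 1.5. Without either control library, the calls of ALAS2, PECAM1, CD68, HORMAD1, VWF, EMCN, ERG, CTSS, HBE1, JAM3, SFRP2, ND1 and FGF2 ended (adjusted p from 0.0507 to 0.353), without control 1 also that of PIWIL1 (0.0581), and without control 2 also those of ACTA2, LYZ, SLA-DRA and CDH1 (0.0511 to 0.162). CD68 and ERG also ended without FO 1, FO 2 or FO 3 (0.0988 to 0.125), and without GF 3 and GF 4 INSL3 did not pass (0.0553) while SOX9 did (0.0348). With RLE size factors, CD68 (0.0513) lost the call. With total counts alone, CD68 (0.0507) lost the call. Without a filter, ALAS2 (0.0501) lost the call. With only the 6 libraries compared, INSL3 (0.0768), ERG (0.0605) and HBE1 (0.0501) lost the call. With only the 6 libraries compared, SOX9 (0.0307) passed. Against a fold of 1.5, ACTA2 (0.0739), CD68 (0.085), ERG (0.0892) and ND1 (0.0512) lost the call. At equal totals, CD68 (0.0616) and HORMAD1 (0.0619) lost the call. With the replicate number as a block, CD68 (0.0965) lost the call. Without FO 1 and GF 3, CD68 (0.0684) and ERG (0.074) lost the call.

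Genes called in the same direction in both grafts against control testis numbered 1464, with 685 higher and 779 lower, and 77 were called in opposite directions. Among them STAR, SCARB1, CYP11A1, KIT, MX1 and HBB fell in both grafts, and PTGDS, ID4, KRT7 and KRT19 rose in both. Independent lists of the same sizes would share 180.5 and 198 genes. Both comparisons use the same 2 control libraries, so 20 sets of unchanged groups were simulated from the measured spread. In these edgeR called 0 shared genes, and 252 shared genes on average at an unadjusted p under 0.05, against 2549 in the data. With no gene changed, the absence of adjusted calls follows from the setting. The simulations thus do not show how far shared controls raise the overlap among genes that changed in either graft alone. Over genes, which are not independent replicates, the fold changes of the 2 comparisons correlated at 0.475, against 0.677 in the simulations, while their covariance was 1.51 against 0.327. The shared count was 843 against a fold of 1.5, 432 without control 1, 344 without control 2 and 3115 without GF 3 and GF 4.

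Each graft library was also compared with control testis by its correlation over 15877 genes, to ask whether GF lies nearer than FO to these control libraries. Pearson r with the control mean was 0.753 ± 0.0757 in GF and 0.844 ± 0.0167 in FO (SD, n = 4), a difference of -0.0918 (exact two-sided permutation test, p = 0.0857, the smallest possible being 0.0286). Without GF 1 the difference was -0.123 with an exact p of 0.0286, and without GF 3 and GF 4 it was -0.0271 with an exact p of 0.467. Over the genes of the testis lists only it was -0.25 (exact p = 0.0571), and without a filter on low counts -0.0473 (exact p = 0.114). The testis lists include the meiosis and spermatid list, whose members PRM1 and PRM2 were at 0 counts in both control libraries. Spermatid transcripts in GF may thus lower r with this reference, but r was not computed without them. A lower r therefore does not show that GF is less like testis in general. On the Sscrofa11.1 build, the reference places DDX4 on chromosome 16 (34879701 to 34983701), PRM1 on chromosome 3 (31861087 to 31861529), CLU on chromosome 14 (11336585 to 11352569), CFI on chromosome 8 (112430824 to 112470844), STAR on chromosome 15 (48377597 to 48385398) and INSL3 on chromosome 2 (59929591 to 59931220).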

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

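The tests of cell shares, depth, GF 3 and GF 4, carry-over and muscle tissue in this part were chosen after the results were seen, and the counts of other splits before. Of 372 groups of 4 libraries (179 genes and 7 library measures, each in FO and GF), 21 held a library far from its 3 fellows by Dixon's test at 95%, and chance alone flags about 1 in 20, or 18.6. In 9 of the 21 the other 3 libraries were at 0, where any count meets the criterion, so that the chance rate does not apply to them. Of the 21, 11 were in FO 1, 7 of them with the other FO libraries at 0. Its total count was 4033509 against 4762361 to 4887878 in the other FO libraries, and its skeletal muscle genes summed to 872 CPM. FO 1 alone among the FO libraries held CCER1, HMGB4, HSPB9, PRM3 and TMIGD3, each at 0.279 CPM, PRM2 at 0.557 CPM and TNP1 at 1.11 CPM. It also had 157 CPM of KRT19 and 63.6 CPM of ZBTB16. In FO 3, ACR was at 0.21 CPM and WT1 at 354 CPM. In GF 3, CD14 was at 2.76 CPM, CLDN1 at 5.87 CPM, CP at 0 CPM, FGF2 at 6.90 CPM and GFRA1 at 0.69 CPM. CXCL14 was at 3.43 CPM in GF 1, RSAD2 at 0.361 CPM in GF 2 and HERC5 at 5.88 CPM in GF 4.

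Among the 35 splits of the 8 graft libraries into 4 and 4, 1, the real one, gave as many genes as the 4205 called by edgeR. The highest of the other 34 was 0 genes, with at most 1934 genes at an unadjusted p under 0.05 (5846 in the real split) and at most 95 called by DESeq2 (5751 in the real split). The real split ranked first, which argues against chance for the number of genes but cannot exclude it, since 1 of 35 is the smallest share possible. The other splits mix FO and GF libraries, so a group difference adds to their spread, and their 0 calls add no separate support. The splits also treat libraries as independent and take no account of the replicate numbers. For the lists chance stays open, since 7 of the 35 splits gave at least the 8 lists of the real one and the highest other gave 10.

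The fibroblast, myeloid, niche signal and complement lists were called lower in GF than in FO with the preset correlation, and none of the 4 was with an estimated one (adjusted p from 0.301 to 0.357). A lower share of every cell type other than germ cells would lower the smooth muscle list as much. The mean log2 CPM of that list less that of the 4 lists was 1.85 ± 0.57 in GF and -0.021 ± 0.20 in FO (SD, n = 4). The difference was 1.87 (exact two-sided permutation p = 0.0286, the smallest possible). The 4 lists were taken because they were lower, and the smooth muscle list after 6 of its members were seen to rise. That choice favours a positive difference, so this p decides nothing. The smooth muscle list alone averaged 6.05 ± 0.27 in GF and 5.50 ± 0.22 in FO, so it did not fall with them. Control testis held over 3 counts in both libraries of 24 of 25, 18 of 18, 15 of 17 and 16 of 19 genes of the 4 lists, and 0, 0, 0 and 0 of their genes were in another list. With the preset correlation, lower depth of the GF libraries is argued against by equal totals, at which 4 of the 4 lists were still called lower, and GF 3 and GF 4 alone by their removal, after which 4 of the 4 were. Whether the lists fell beyond the correlation of their genes stays open. A lower share of all cells but germ cells, as the only change, is argued against by the smooth muscle list. It averaged 6.05 ± 0.27 in GF and 5.50 ± 0.22 in FO, though it was chosen after members were seen to rise. Such a fall beside other changes stays open. So do a lower share of these particular cells and lower expression within them. Chance for the number of lists and an effect of the germ cells, which the design names, also stay open. None of these was told from the others by any test.

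DDX4 and DAZL had 39 counts over the 4 FO libraries, 3, 18, 15 and 3 in FO 1 to FO 4. Carry-over of GF material would bring them in the proportion of PRM1, PRM2 and TNP1, of which FO held 17 counts and GF 11675. The upper 95% limit of that proportion, 0.233%, allows 4.55 counts, and FO 2 and FO 3 held 0 counts of the 3 spermatid genes. FO 1 held 16 of the 17 spermatid counts, beside 3 counts of DDX4 and DAZL. The pooled limit therefore does not argue against carry-over of GF material into FO 1 alone, which stays open. Carry-over from control testis in the proportion of HBB allows 1.64 counts. Both limits rest on pooled counts and cover counting error only. They treat reads as independent, which reads without molecular identifiers are not, and no p-value is given for them. The test was first run on the 10 early germ cell genes called in GF versus FO, of which FO held 2263 counts, 2119 of them ZBTB16 and DMRT1, and was then narrowed to DDX4 and DAZL; a few germ cells in the FO grafts and low expression in other cells stay open, untested.

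Skeletal muscle transcripts stood out in FO 1 and GF 3. Of the 14 genes of the list in the table, 2 had over 3 counts in both control libraries and 0 were in another list. Carry-over between these libraries would keep the genes in 1 ratio. The ratio of FO 1 to GF 3 counts ran from 0.439 for MYH4 to 23.8 for CKM, 54.2-fold apart. These extremes rest on 18 and 41 counts of MYH4 and on 214 and 9 counts of CKM. A chi-square test with simulated tables gave p = 1e-04, the smallest the simulations can give. It covers counting error only and treats reads as independent, which reads without molecular identifiers are not. Of the detected members, 12 of 12 were higher in FO 1, and 10 of 11 in GF 3, than in every other library of the group, and the most abundant were ACTA1 at 818 and 210 counts and TTN at 751 and 322 counts. The sum of the same list is what made the 2 libraries stand out, so these counts describe the pattern and test no source of it. Muscle tissue in the samples stays open. Whether the transcripts are of pig or mouse, and whether they came from tissue at the graft site or otherwise, was not tested.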

How the results depend on the processing

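The alternatives that leave out GF 3 and GF 4 or FO 1 and GF 3, thin the libraries, or block the shared calls were chosen after seeing the data. Over the planned and added alternatives, the counts of called genes stayed within 1.5 times the reported ones except as follows. Against a fold of 1.5, a stricter test by construction, 2456 genes were called in GF versus FO, 2658 in GF versus control testis, 1833 in FO versus control testis and 843 in both grafts. With only the 6 libraries compared, 2201 (GF) and 6600 (FO) genes differed from control testis, against 4091 and 2972 in the fit of 10. Which graft had more calls thus depended on the libraries in the fit. Without GF 3 and GF 4, 6510 genes differed in FO versus control testis and 3115 in both grafts. Without FO 1 and GF 3, 2312 differed in GF versus FO. In FO versus control testis, GF libraries enter only through the shared filter, scaling and spread estimate. Which of these moved the count was not tested, nor was the cause in the other cases. With 1 library left out, counts ranged from 2902 to 4842 in GF versus FO, where the lowest value left out FO 1. Against control testis they ranged from 1141 to 4729 in GF, 796 to 2263 in FO and 344 to 1873 for both grafts. The lowest values against control testis leave 1 control library, assumed to vary like the other groups. Lists called numbered 0, 1 and 1 with an estimated correlation and 13, 20 and 14 with fry, against 8, 13 and 14, and 8 to 10, 13 to 16 and 13 to 14 with 1 library left out. The difference in similarity kept its sign, from -0.123 to -0.0631 with 1 library left out (exact p from 0.0286 to 0.143). It was -0.25 over the testis lists only (exact p = 0.0571), -0.112 with a prior count of 0.5 and -0.0473 without a filter. Same-number FO and GF libraries correlated at 0.105 to 0.258 over the genes of GF versus FO, but at 0.055 to 0.218 over those of the fit of 10 libraries, and 2 of 4 FO libraries fitted their own number best, so the numbers were not taken as pairs. With the number as a block, 4335, 3282 and 3219 genes, 8, 14 and 14 lists and 1293 shared genes were called, and the similarity p was 0.25.

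Of the 94 genes named in GF versus FO, 11 lost their call in at least 1 alternative. Of the 88 genes named in GF versus control testis, 20 lost their call in at least 1 alternative. Of the 93 genes named in FO versus control testis, 19 lost their call in at least 1 alternative. Direction turned only for 5 named genes, none of which passed there. With 1 library left out, log2 fold changes ran from -0.34 to 0.35 for CYP11A1, -0.035 to 0.23 for KIT, -0.36 to 0.46 for STAR, -0.45 to 0.058 for UCHL1 in GF versus FO. With total counts alone they were STAR 0.042, CYP11A1 0.030. With the block they were STAR 0.073, CYP11A1 0.059, (in FO versus control testis) MYH11 -0.065. Without FO 1 and GF 3 it was KIT -0.11. The cause was not tested. Genes under about 3 counts per library cannot be placed above or below each other at this depth.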

Other observations

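Pathway and junction genes of GF and FO differed in both directions. Of the Hedgehog and Wnt response list, of 16 tested members 2 rose, 5 fell and 9 did not pass (2 rose and 7 fell adjusted over the list alone), and the list did not pass (adjusted p = 0.0873). The Hedgehog receptor and target PTCH1 (1.13) rose in GF, while the secreted Wnt antagonists SFRP4 (-3.07) and SFRP1 (-2.45) fell. Of the tight junction and cell adhesion list, of 12 tested members 2 rose, 4 fell and 6 did not pass (2 rose and 5 fell adjusted over the list alone) (adjusted p = 0.372), with ESPN (2.84), an actin bundler, and NECTIN2 (1.21) higher and CDH2 (-1.56) and CLDN1 (-2.13) lower. Of the interferon response list, of 12 tested members 2 rose, 7 fell and 3 did not pass (2 rose and 7 fell adjusted over the list alone), and the list did not pass (adjusted p = 0.0508). IFIT1 (-3.37), MX1 (-2.14) and OAS2 (-1.66) fell. HBE1 had 97, 27, 32 and 275 counts in FO 1 to FO 4, 18, 22, 5 and 0 in GF 1 to GF 4, and 1 and 2 in the control libraries, where HBB had 18410 and 25841. Leaving out GF 1 moved IFIT1 (to -4.23).

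Other lists did not pass in GF versus FO. For the adipocyte list, of 10 tested members 3 rose and 7 did not pass (3 rose adjusted over the list alone) (adjusted p = 0.391). For the Schwann and neural cell list, of 5 tested members 2 rose and 3 did not pass (2 rose adjusted over the list alone) (adjusted p = 0.372). For the cartilage and bone list, of 5 tested members 2 rose, 2 fell and 1 did not pass (2 rose and 2 fell adjusted over the list alone) (adjusted p = 0.95). For the cholesterol synthesis list, of 14 tested members 4 rose and 10 did not pass (4 rose adjusted over the list alone) (adjusted p = 0.372). For the TGF-beta response and matrix crosslinking list, of 12 tested members 4 fell and 8 did not pass (1 rose and 4 fell adjusted over the list alone) (adjusted p = 0.123). For the immediate early and heat shock list, of 14 tested members 1 rose, 2 fell and 11 did not pass (1 rose and 2 fell adjusted over the list alone) (adjusted p = 0.452). For the hypoxia and glycolysis list, of 16 tested members 4 rose, 3 fell and 9 did not pass (4 rose and 3 fell adjusted over the list alone) (adjusted p = 0.838). In the lymphocyte, skeletal muscle, epidermis, epithelium and erythrocyte lists fewer than 5 members could be tested, and 2 of 3, 0 of 2, 2 of 4, 1 of 4 and 1 of 3 tested members were called.

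Against control testis, these lists did not pass in GF. For the lymphocyte list, of 5 tested members 2 fell and 3 did not pass (1 rose and 2 fell adjusted over the list alone) (adjusted p = 0.281). For the adipocyte list, of 11 tested members 4 rose, 2 fell and 5 did not pass (4 rose and 3 fell adjusted over the list alone) (adjusted p = 0.389). For the skeletal muscle list, of 11 tested members 11 did not pass (0 passed adjusted over the list alone) (adjusted p = 0.736). For the Schwann and neural cell list, of 7 tested members 2 rose and 5 did not pass (4 rose adjusted over the list alone) (adjusted p = 0.105). For the cartilage and bone list, of 7 tested members 1 rose, 1 fell and 5 did not pass (1 rose and 2 fell adjusted over the list alone) (adjusted p = 0.736). For the tight junction and cell adhesion of the blood-testis barrier list, of 13 tested members 3 rose and 10 did not pass (3 rose adjusted over the list alone) (adjusted p = 0.0577). For the signals of the germ cell niche list, of 14 tested members 1 rose, 5 fell and 8 did not pass (1 rose and 5 fell adjusted over the list alone) (adjusted p = 0.0631). For the TGF-beta response and matrix crosslinking list, of 13 tested members 1 rose, 2 fell and 10 did not pass (1 rose and 3 fell adjusted over the list alone) (adjusted p = 0.0876). For the Hedgehog and Wnt response list, of 16 tested members 3 rose, 2 fell and 11 did not pass (4 rose and 2 fell adjusted over the list alone) (adjusted p = 0.243). For the immediate early and heat shock list, of 15 tested members 3 rose, 2 fell and 10 did not pass (3 rose and 2 fell adjusted over the list alone) (adjusted p = 0.809). For the hypoxia and glycolysis list, of 18 tested members 3 rose, 5 fell and 10 did not pass (4 rose and 7 fell adjusted over the list alone) (adjusted p = 0.449). For the mitochondrial genome list, of 13 tested members 2 rose, 2 fell and 9 did not pass (2 rose and 2 fell adjusted over the list alone) (adjusted p = 0.858). Median, mean and test differed in sign for cartilage and bone, immediate early, hypoxia and mitochondrial genome genes. In FO versus control testis, the remaining lists did not pass either. For the lymphocyte list, of 5 tested members 1 fell and 4 did not pass (1 fell adjusted over the list alone) (adjusted p = 0.361). For the adipocyte list, of 11 tested members 2 fell and 9 did not pass (1 rose and 3 fell adjusted over the list alone) (adjusted p = 0.907). For the skeletal muscle list, of 11 tested members 11 did not pass (0 passed adjusted over the list alone) (adjusted p = 0.431). For the peritubular myoid and smooth muscle list, of 15 tested members 4 rose, 1 fell and 10 did not pass (4 rose and 1 fell adjusted over the list alone) (adjusted p = 0.531). For the Schwann and neural cell list, of 7 tested members 2 rose and 5 did not pass (3 rose and 1 fell adjusted over the list alone) (adjusted p = 0.113). For the cartilage and bone list, of 7 tested members 2 rose, 2 fell and 3 did not pass (2 rose and 2 fell adjusted over the list alone) (adjusted p = 0.907). For the TGF-beta response and matrix crosslinking list, of 13 tested members 1 rose and 12 did not pass (1 rose adjusted over the list alone) (adjusted p = 0.902). For the immediate early and heat shock list, of 15 tested members 2 rose, 1 fell and 12 did not pass (2 rose and 1 fell adjusted over the list alone) (adjusted p = 0.596). For the hypoxia and glycolysis list, of 18 tested members 3 rose, 3 fell and 12 did not pass (3 rose and 5 fell adjusted over the list alone) (adjusted p = 0.635). For the complement, chemokines and cytokines list, of 14 tested members 3 rose, 3 fell and 8 did not pass (3 rose and 4 fell adjusted over the list alone) (adjusted p = 0.983). Median, mean and test differed in sign for adipocyte, cartilage and bone, niche signal and hypoxia genes. The epidermis list had 4 tested members in each comparison and was not tested as a list.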
